A study of Mus musculus with 4 samples.

How the data were processed

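RNA from 4 samples of cultured mouse CD4+ T cells was measured on expression arrays of 45101 probe sets, 2 with TGFb1 alone and 2 with TGFb1 plus progesterone. Per the labels' protocols, the cells were grown in RPMI medium with 10% serum, and biotin-labelled cRNA was made from 2 ug of total RNA. The deposited values are signal intensity on a linear scale, made with MAS5 per the submitters' processing notes, which give no version. MAS5 combines the probes of a set within each array, and the scaling that the authors applied is not given in the sources used here. No detection call was used, so a dim signal has no stated limit of detection. The number of arrays limits the precision, with 2 residual degrees of freedom.

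Groups and replicate numbers were taken from the sample labels. The design, gene lists, alternatives and rule for named genes were fixed before the data were examined. Values were to be used as deposited if the trimmed means of the arrays (2% off each end) lay within 5% of each other, and quantile normalised otherwise. Their highest over lowest was 1.43, so quantile normalisation was used. Values were then taken as log2(signal + 16), and folds on this scale are smaller than true folds for dim genes. The 64 control probe sets were left out, and a probe set was kept if its mean over the 4 arrays lay above the median of all, which left 22518.

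Gene names came from the platform annotation, with symbols looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which matched 34741 probe sets and also gave the chromosome. No coordinates are given because no build is stated for the array. Of the 45037 other probe sets, 34945 had 1 gene, 932 several and 9160 none. Only probe sets with 1 gene were named. Each gene was represented by its single-gene probe set with the highest mean, giving 10501 genes. The range over a gene's probe sets is stated for some of the genes named. Other kept probe sets had the opposite sign for Ighm (0.20), Mtor (-0.35), Nr3c1 (-0.22), Tgfb1 (0.13) and H2-Ab1 (-0.14).

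Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), progesterone minus TGFb1 alone, without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p of a gene comes from this test. Genes separated needed a mean fold of 2 or more and a gap of 1.5-fold between groups. With 4 arrays there are 3 ways to split them 2 against 2, so no permutation share can fall below 0.333, and an unchanged gene has non-overlapping groups with a chance of 33.3%. Of 28 gene lists, the 25 with 5 or more tested members were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists. No list call held with an estimated correlation, where 1 list had an unadjusted p under 0.05. With an estimated correlation camera takes its statistic on the 2 residual degrees of freedom, so little could pass. Fatty acid synthesis genes had an estimated correlation of -0.040, below the preset value, and still had a camera adjusted p = 0.407 there. A call lost in this way therefore does not show that correlation between genes accounts for it. Lists of T cell identity, further myeloid, Y-linked and X-linked escape genes were added after the data were seen. Fry, which tests whether a list's genes move on balance one way, was run as an alternative. In all, 8 of the lists hold markers of other cell types that the cultures could contain.

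The rule for named genes took up to 12 rising and 12 falling genes by size of change among those that passed and did not overlap between groups, up to 4 members per list by the moderated statistic, the 2 brightest members of each marker list, and a fixed set of regulators and receptors. Members of that set without a usable probe set are not reported here. On simulated arrays with the spread of these 10501 genes and 200 changed genes, the test of progesterone against TGFb1 recovered 15.2% of genes changed 1.5-fold, 59.3% of those changed 2-fold and 94.5% of those changed 4-fold, and 4.26% of its calls were false. The list test found a simulated shift of -0.5 of the cell cycle list in 20 of 20 simulations. The simulated genes were drawn independently of each other, whereas in the data the cell cycle list had an estimated correlation of 0.77. The simulations therefore do not show how either test behaves when genes are correlated.

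Alternatives were other pseudocounts (0 and 64), values as deposited, centring each array on its median, no filter, the upper 25% by level, eBayes without a trend, a robust variance model, the mean of a gene's probe sets, leaving out _x_at and _s_at probe sets, the replicate number as a block, leaving out each array, other thresholds and other list tests. Centring used the median of all probe sets before the level filter. Leaving out the genes of the X and Y chromosomes was added after the data were seen. When an array is left out, the lone array of its group is assumed to vary like the other group. The filter and the choice of each gene's probe set were repeated under each alternative.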

Results

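Gene expression was measured in mouse CD4+ T cells, the helper class of T lymphocytes, taken as naive cells from spleen, peripheral lymph nodes and mesenteric lymph nodes. The cells were cultured for 7 days with concanavalin A, a plant lectin that activates T cells, at 2.5 ug/ml. One group of 2 arrays came from cells given TGFb1 alone at 1 ng/ml, a cytokine that drives naive CD4+ cells towards a regulatory state. The other group of 2 arrays came from cells given the same TGFb1 together with progesterone, a steroid hormone, at 2000 ng/ml. Each array held 45101 probe sets. The trimmed mean signal was 155.4 and 146.2 in the TGFb1 arrays and 138.5 and 108.3 in the progesterone arrays, so signals were quantile normalised. Over the 10501 genes tested, arrays of the same group correlated at r = 0.982 (TGFb1) and 0.985 (progesterone), and arrays of different groups at 0.937 to 0.961, across genes, which are not independent replicates. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. All changes below are log2 differences, progesterone minus TGFb1 alone, on the log2(signal + 16) scale, which understates the change of dim genes, with the standard error of the limma fit and n = 2 per group.

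The design asks one question, which genes progesterone changes in T cells that also receive TGFb1. In the progesterone arrays 20 of 28 cell cycle genes and 14 of 20 cholesterol synthesis genes fell, while 8 of 19 TGFb response genes, led by the integrin chain gene Itgae, rose and 1 fell. These lists were called with a preset correlation and not with an estimated correlation (adjusted p = 0.511 for cell cycle genes and adjusted p = 0.407 for both others). The latter test has only 2 residual degrees of freedom here, so its failures, here and below, decide little. Of 10501 genes, 857 changed by limma, with 314 up and 543 down, and 386 of these changed at least 2-fold, with 80 up and 306 down. By a description that needs no variance model, 405 genes were separated between the groups (90 up, 315 down), meaning a mean fold of 2 or more and a gap of 1.5-fold between the nearest arrays. The other 2 ways of splitting the 4 arrays into pairs separated 10 and 3 genes. Over all probe sets, 1348 of 22518 changed, 532 up and 816 down. The balance of rises and falls depended on scaling. With the values as deposited 142 genes rose and 795 fell, against an all-gene median of -0.22. With each array centred on its median 148 rose and 3631 fell, against an all-gene median of -0.34. The centring median was that of all probe sets before the level filter, a dim signal. It was 23.7 and 23.6 in the TGFb1 arrays and 30.0 and 24.5 in the progesterone arrays. Centring therefore did not align the tested genes, and its many falls, here and below, include this shift. Among the rises named below, Eif2s3x, Kdm6a, Ccnd2, Ikzf4, Stat3, Skil, Il7r, Cxcr4, Sesn3, Gnl3, Nop2, Irgm1 and Ctss did not pass with the values as deposited. In that fit the prior degrees of freedom were infinite, against 5.51 in the main fit. Each gene's own spread was then not used, so calls gained or lost as deposited reflect the variance model as well as scaling. Without progesterone replicate 1 the count of changed genes was 407, and without progesterone replicate 2 it was 246.

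The groups also differed in genes of the sex chromosomes. Xist, the non-coding RNA transcribed from the inactive X chromosome of female cells, had the largest rise, 5.58 ± 0.17 (SE), with an adjusted p = 2.1e-05. Its deposited signals were 9.52 and 9.70 in the TGFb1 arrays and 1390 and 825 in the progesterone arrays. Eif2s3y had the largest fall, -5.18 ± 0.18, with deposited signals of 689 and 727 in the TGFb1 arrays and 4.25 and 0.49 in the progesterone arrays. Kdm5d (-3.77), Uty (-2.56) and Orly (-2.03) fell as well, so all 4 tested Y-linked genes fell. Over each gene's probe sets the values ran from 3.09 to 5.82 for Xist, from -3.77 to -1.30 for Kdm5d and from -2.03 to -0.69 for Orly. Of 6 X-linked genes known to escape inactivation, all 6 were higher in the progesterone arrays after quantile normalisation (median 0.36), and Eif2s3x (0.44) and Kdm6a (0.49) passed the test. With the values as deposited 4 of the 6 were higher (median 0.0397) and with each array centred on its median 2 were (median -0.084), and neither gene passed. The list median lay above that of all genes by 0.26 in both. Every gene group described below was compared between arrays that also differed in this way. The 857 changed genes were 26 of 307 tested genes on the X, 4 of 4 on the Y and 827 of the 10190 others. The others include any gene without a stated chromosome.

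**Figure D1:**
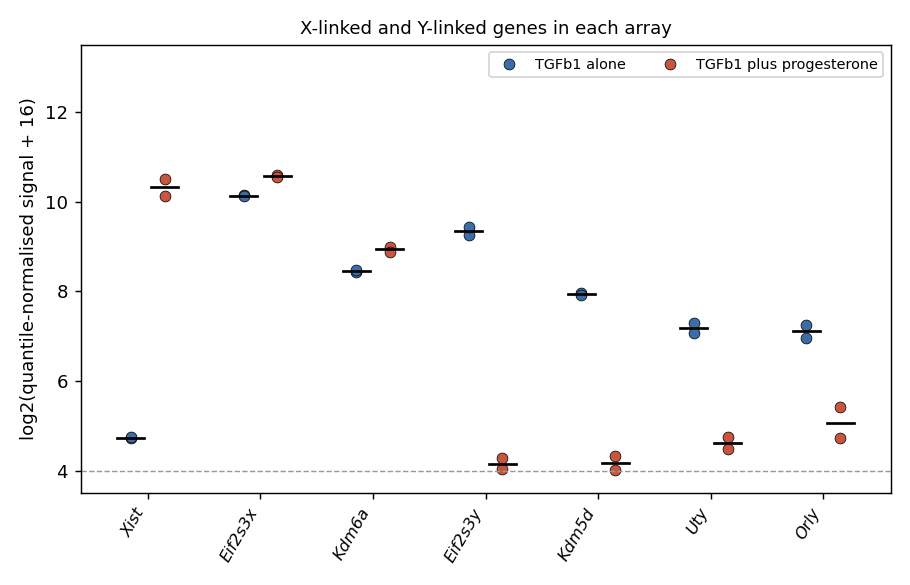
Level of 3 X-linked genes and 4 Y-linked genes in each array, as log2(quantile-normalised signal + 16) on the vertical axis, with a point per array, a bar at each group's mean (n = 2) and a dashed line at the value of a signal of 0. Xist lies at 4.74 on average in the TGFb1 arrays and 10.3 in the progesterone arrays, and Eif2s3y at 9.34 and 4.16.

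Cell cycle genes fell together. Of 28 tested members, 20 fell and 1 rose, with a list median of -2.17 (camera adjusted p = 1.3e-17; adjusted over the list alone, 22 fell and 1 rose). With an estimated correlation between genes the list had an adjusted p = 0.511, and by fry an adjusted p = 0.106. Birc5, a survival and chromosome segregation factor, fell by 3.04 ± 0.27 (adjusted p = 0.00171). Mki67, the Ki-67 proliferation antigen, fell by 2.66 ± 0.27, and falls were also seen for the ribonucleotide reductase subunit gene Rrm2 (-2.64 ± 0.27) and the topoisomerase gene Top2a (-2.61 ± 0.27). The member that rose was the cyclin gene Ccnd2, at 0.52 (adjusted p = 0.0167), singled out after its value was seen. Ccnd2 was at 0.0766 with the values as deposited and -0.0471 with each array centred on its median, and it did not pass there, with no intensity trend, with the mean of its probe sets or without either progesterone array. Among the largest falls named by rank were also the chromosomal passenger gene Cdca8 (-3.28), the spindle checkpoint kinase gene Bub1 (-3.26), the ubiquitin-conjugating enzyme gene Ube2c (-3.18), the cohesin acetyltransferase gene Esco2 (-3.04), the spindle protein gene Nusap1 (-3.00) and the kinesin gene Kif2c (-2.87). For Kif2c the gene's other probe sets reached -0.19, and for Nusap1 -1.45. Depdc1b (-3.04), Shcbp1 (-2.94) and the uncharacterised gene 9630013D21Rik (-2.94) completed the largest falls.

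**Figure D2:**
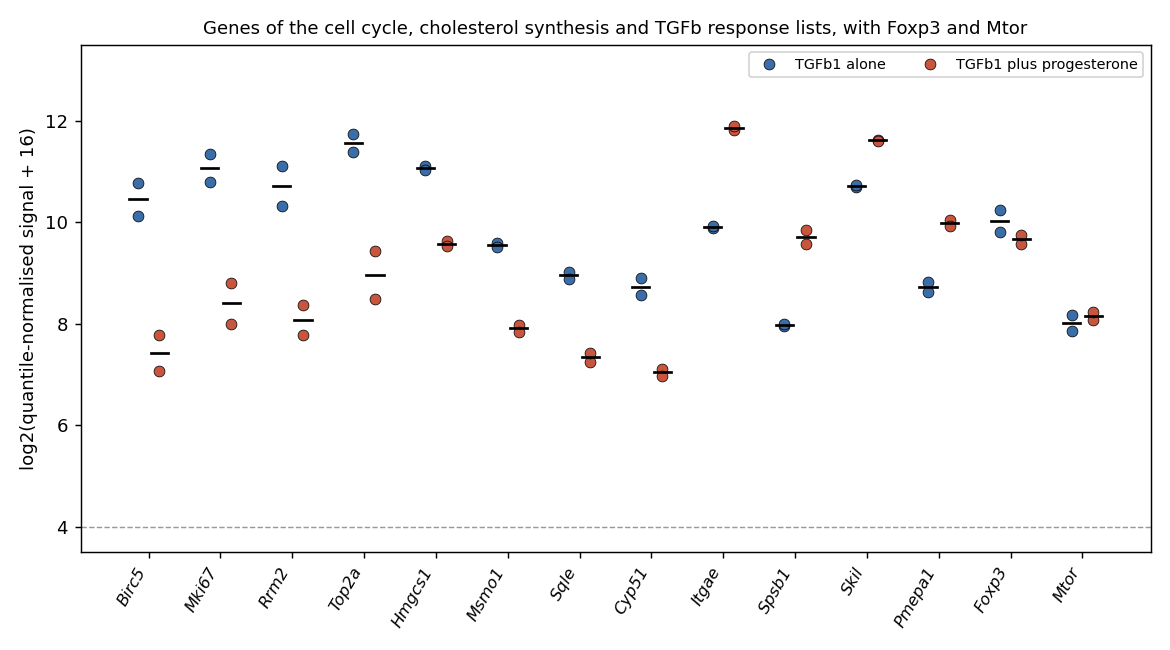
Level of 14 genes in each array, as log2(quantile-normalised signal + 16) on the vertical axis, with a point per array, a bar at each group's mean (n = 2) and a dashed line at the value of a signal of 0. Both progesterone arrays lie below both TGFb1 arrays for the cell cycle and cholesterol synthesis genes and above them for Itgae, Spsb1, Skil and Pmepa1.

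Genes of sterol and fatty acid synthesis were lower with progesterone. Of 20 tested cholesterol synthesis genes 14 fell and none rose, with a median of -0.92 (camera adjusted p = 2.2e-15; 17 fell when adjusted over the list alone), and an adjusted p = 0.407 with an estimated correlation. The HMG-CoA synthase gene Hmgcs1 changed by -1.498 ± 0.093 (adjusted p = 0.000633), the sterol oxidase gene Msmo1 by -1.64 ± 0.12, the squalene epoxidase gene Sqle by -1.62 ± 0.14 and the lanosterol demethylase gene Cyp51 by -1.68 ± 0.16. Of 14 tested fatty acid synthesis genes 6 fell, with a median of -0.49 (camera adjusted p = 8.3e-07; 8 fell when adjusted over the list alone), and an adjusted p = 0.407 with an estimated correlation. The desaturase gene Scd2 changed by -1.14 ± 0.10, the desaturase gene Fads2 by -1.39 ± 0.25, the acyl-CoA synthetase gene Acsl3 by -0.97 ± 0.15 and the elongase gene Elovl5 by -0.57 ± 0.09. Without progesterone replicate 2, 9 cholesterol synthesis genes and 1 fatty acid synthesis gene fell. Among 10 LXR target genes, which sterols regulate, 2 rose, the apolipoprotein gene Apoe (1.42 ± 0.22) and the sterol transporter gene Abca1 (0.99 ± 0.21), and the list was not called (adjusted p = 0.452; 2 up and 1 down when adjusted over the list alone). Apoe was dim, with deposited signals of 19.3 and 18.1 in the TGFb1 arrays and 94.6 and 64.5 in the progesterone arrays. The probe sets of Abca1 lay between 0.35 and 0.99.

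TGFb response genes rose, 8 up and 1 down of 19 tested, with a median of 0.55 (camera adjusted p = 8.4e-05; 10 up and 1 down when adjusted over the list alone), and an adjusted p = 0.407 with an estimated correlation. Itgae, which encodes the CD103 integrin chain, rose by 1.96 ± 0.08 (adjusted p = 8.5e-05), a 3.89-fold rise. Spsb1 rose by 1.73 ± 0.13, the SMAD co-repressor gene Skil by 0.90 ± 0.08 and Pmepa1, a feedback inhibitor of TGFb signalling, by 1.27 ± 0.12. The member that fell was the cell cycle inhibitor gene Cdkn1a, at -1.28 (adjusted p = 0.00232), singled out after its value was seen. Without progesterone replicate 2, 4 members rose. With the values as deposited 4 rose and 1 fell (median 0.21), and with each array centred on its median 4 rose and 3 fell (median 0.08). Tgfb1 itself did not pass the test, at -0.31 ± 0.14 (adjusted p = 0.238). Homing receptor genes had 4 of 19 up and none down, with a median of 0.27 (camera adjusted p = 0.00935, and adjusted p = 0.407 with an estimated correlation; 7 up and 2 down when adjusted over the list alone). Besides Itgae they were the chemokine receptor genes Cxcr4 (0.83 ± 0.10) and Ccr9 (0.82 ± 0.19) and the gut homing receptor gene Gpr15 (1.33 ± 0.21). The median was -0.0786 with the values as deposited (4 up and 1 down) and -0.20 with each array centred on its median (4 up and 5 down), with the test still upward. Leaving out either progesterone array left 2 up, and leaving out TGFb1 replicate 2 gave 7 up and 2 down.

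Lists of genes of regulatory T cells (Treg), of Th17 cells and of the pathway of mTOR, a growth kinase, were fixed in advance. Treg genes had 2 up and 3 down of 21 (median 0.00; camera adjusted p = 0.764; 3 up and 6 down when adjusted over the list alone), 1 up and 5 down with the values as deposited and 2 up and 11 down with each array centred on its median. Foxp3, the lineage factor of regulatory T cells, was at -0.37 ± 0.15 with an adjusted p = 0.195, and the settings in which it passed the test as a fall included leaving out TGFb1 replicate 1 (-0.57, adjusted p = 0.0204) and centring each array on its median (-0.86). Without TGFb1 replicate 2 it was at -0.16 (adjusted p = 0.462). Its adjusted p ran from 0.00193 to 0.547 over the alternatives. Itgae, also a member of this list, rose by 1.96 ± 0.08 and Ikzf4 by 0.91 ± 0.11, whereas Ikzf2 (-0.76 ± 0.13) and the costimulatory receptor gene Tnfrsf9 (-0.89 ± 0.11) fell. Th17 genes had 2 up and 2 down of 10 (median 0.26; camera adjusted p = 0.172; 4 up and 2 down when adjusted over the list alone). With the values as deposited the Th17 list was called as higher (camera adjusted p = 0.033, and adjusted p = 0.94 with an estimated correlation) although its median was then -0.0776. The transcription factor gene Maf rose by 2.73 ± 0.16, with its probe sets between 0.29 and 2.73, and Batf (-0.71 ± 0.11) and Irf4 (-0.51 ± 0.09) fell. Stat3 rose by 0.41 ± 0.10, but was at -0.03 with the values as deposited and -0.15 with each array centred on its median. Il17a lay under the level filter, with deposited signals of 10.7, 15.7, 9.23 and 22.2. Of 23 genes for mTOR pathway components, 1 rose and 2 fell (median -0.03; camera adjusted p = 0.846; 1 up and 3 down when adjusted over the list alone), with 12 down when each array was centred on its median, and Mtor was at 0.13 ± 0.16 (adjusted p = 0.648). The members that passed were the sestrin genes, with Sesn3 at 0.60 ± 0.11, Sesn1 at -0.41 ± 0.10 and Sesn2 at -0.69 ± 0.16.

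**Figure D3:**
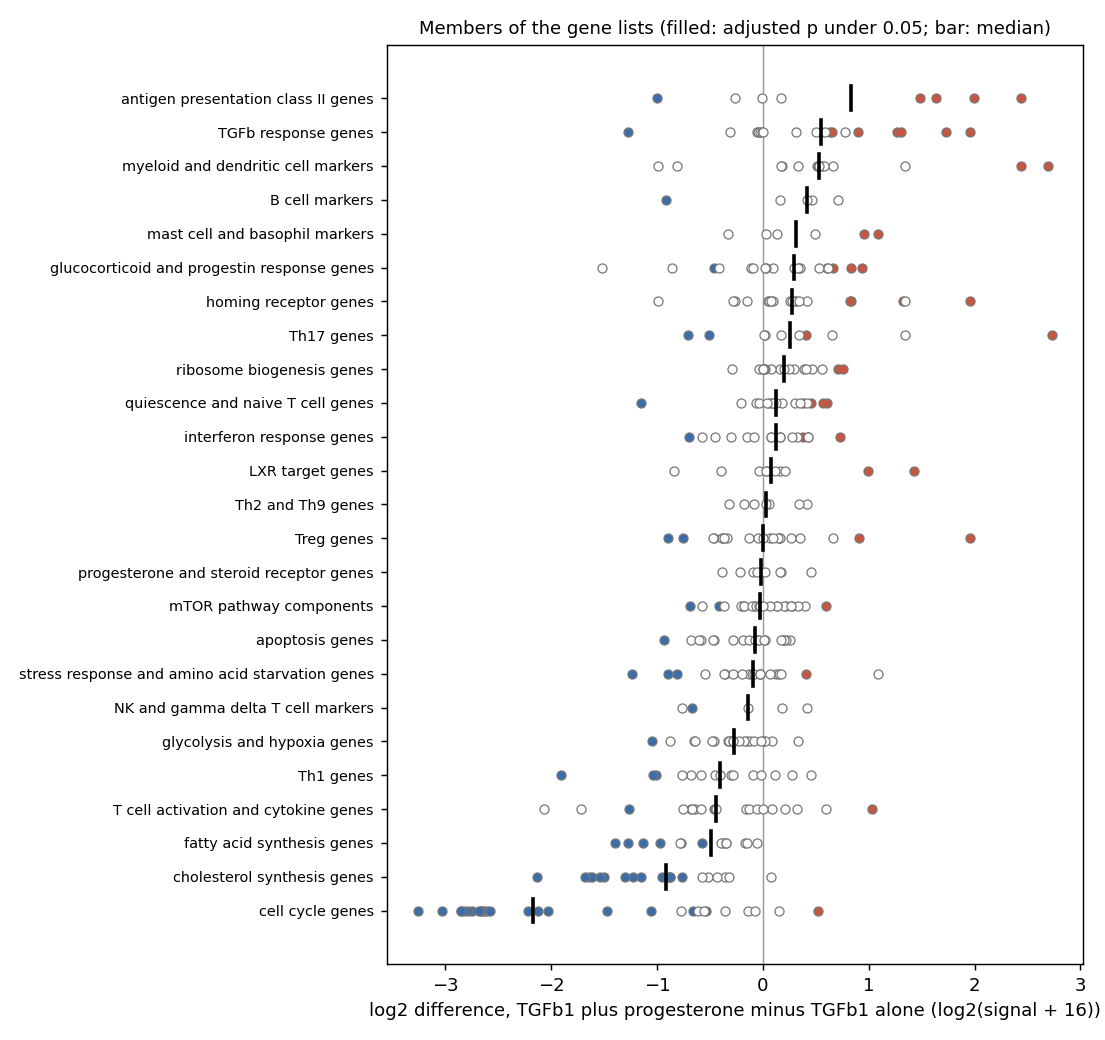
Log2 difference between the groups, on the horizontal axis, of each tested member of the 25 gene lists, with a point per gene, filled where the adjusted p was under 0.05, and a bar at each list's median. The medians run from -2.17 for cell cycle genes to 0.83 for antigen presentation class II genes.

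Effector genes were lower in part. Th1 genes had 3 of 15 down (median -0.41; camera adjusted p = 0.0133, and adjusted p = 0.407 with an estimated correlation; 5 down when adjusted over the list alone). They were the interleukin 18 receptor gene Il18r1 (-1.91 ± 0.29), the granzyme gene Gzmb (-1.04 ± 0.22) and Nkg7 (-1.01 ± 0.14). T cell activation and cytokine genes had 1 up and 3 down of 19 (median -0.45; camera adjusted p = 0.0207, and adjusted p = 0.407 with an estimated correlation; 1 up and 5 down when adjusted over the list alone). The early response genes Nr4a3 (-1.26 ± 0.12) and Nr4a1 (-0.68 ± 0.12) and the growth regulator gene Myc (-0.46 ± 0.10) fell, and Egr2 rose (1.03 ± 0.21, with its probe sets between 0.48 and 1.03). Without TGFb1 replicate 1 Egr2 was at 0.19, but that value came from another probe set. The probe set used with all arrays was at 6.68 and 6.21 in the TGFb1 arrays and 7.33 and 7.62 in the progesterone arrays. The activation call was lost without TGFb1 replicate 2 (adjusted p = 0.0789), without progesterone replicate 2 (adjusted p = 0.0508) and with each array centred on its median (adjusted p = 0.14), and the Th1 call with that centring (adjusted p = 0.18). With each array centred on its median 8 Th1 genes, 11 activation genes and 15 glycolysis genes fell. Glycolysis and hypoxia genes had 1 of 22 down, Aldoc (-1.05 ± 0.25, and -0.64 without progesterone replicate 2), with a median of -0.28 (camera adjusted p = 0.0227, and adjusted p = 0.653 with an estimated correlation; none when adjusted over the list alone). That call was lost without TGFb1 replicate 1 (adjusted p = 0.804), without progesterone replicate 2 (adjusted p = 0.932) and with no intensity trend (adjusted p = 0.0505).

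Ribosome biogenesis genes had 2 of 17 up, Gnl3 (0.71 ± 0.13) and Nop2 (0.76 ± 0.15), with a median of 0.20 (camera adjusted p = 0.0251, and adjusted p = 0.627 with an estimated correlation; 3 up when adjusted over the list alone). Quiescence and naive T cell genes had 4 up and 1 down of 17 (median 0.13; camera adjusted p = 0.0307, and adjusted p = 0.561 with an estimated correlation; 7 up and 2 down when adjusted over the list alone). The interleukin 7 receptor gene Il7r (0.60 ± 0.12) was among those that rose and Dapl1 fell (-1.15 ± 0.13). Neither list was called with the values as deposited, where the medians were -0.02 for ribosome biogenesis genes and -0.27 for quiescence genes. As deposited no gene of either list rose by limma and 1 quiescence gene fell. With each array centred on its median, 2 ribosome biogenesis genes and 8 quiescence genes fell and no gene of either list rose. Without TGFb1 replicate 1 the adjusted p was 0.255 for ribosome biogenesis genes and 0.055 for quiescence genes, and with each array centred on its median it was 0.14 and 0.436. The quiescence call was also lost without progesterone replicate 2 (adjusted p = 0.0715), in the upper 25% by level (0.0637), with no intensity trend (0.122), with the mean of a gene's probe sets (0.0525) and without _x_at and _s_at probe sets (0.0609).

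Genes that answer glucocorticoids and progestins had 4 up and 1 down of 19 (median 0.29; camera adjusted p = 0.096; 7 up and 4 down when adjusted over the list alone). That balance turned with scaling, to 1 up and 4 down with the values as deposited (median -0.11) and 1 up and 5 down with each array centred on its median (median -0.23). Cxcr4, Il7r and the transglutaminase gene Tgm2 (0.94 ± 0.15) rose and Bcl6 fell (-0.46 ± 0.11). The steroid response genes Tsc22d3 (0.29 ± 0.10, adjusted p = 0.127) and Fkbp5 (-0.11 ± 0.17, adjusted p = 0.741) did not pass. None of 8 steroid receptor genes passed limma's test, and 0 had an unadjusted p under 0.05, with the glucocorticoid receptor gene Nr3c1 at 0.16 ± 0.12, and the membrane progesterone receptor component genes Pgrmc1 at 0.17 ± 0.12 and Pgrmc2 at -0.09 ± 0.12. The progesterone receptor gene Pgr lay under the level filter, with deposited signals of 16.4, 18.5, 6.16 and 22.6. Th2 and Th9 genes (none of 7, and 1 at an unadjusted p under 0.05), interferon response genes (2 up and 1 down of 16), stress response genes (1 up and 3 down of 20) and apoptosis genes (1 down of 19) were not called as lists, and the counts adjusted over the list alone were the same. As deposited the counts were 0 up and 1 down for interferon, 1 up and 4 down for stress response and 0 up and 3 down for apoptosis genes. With each array centred on its median they were 0 up and 4 down, 1 up and 12 down, and 0 up and 8 down, and 3 Th2 and Th9 genes and 3 steroid receptor genes fell. The stress response list was called as lower without TGFb1 replicate 1 (adjusted p = 0.0481) or progesterone replicate 1 (adjusted p = 0.0417), and the apoptosis list with the mean of a gene's probe sets (adjusted p = 0.0317). Among them, Irgm1 rose by 0.73 ± 0.09 (0.34 as deposited, where it did not pass), and the serine synthesis genes Phgdh (-0.81 ± 0.10) and Psat1 (-1.24 ± 0.22) and the cell death gene Pmaip1 (-0.94 ± 0.13) fell.

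Markers of other cell types also moved with the group. Myeloid and dendritic cell markers had 3 of 14 up (median 0.53; camera adjusted p = 0.0133, and adjusted p = 0.57 with an estimated correlation; 4 up and 1 down when adjusted over the list alone), namely the lysozyme gene Lyz2 (2.69 ± 0.39), S100a8 (2.44 ± 0.58, and 1.46 without TGFb1 replicate 2) and the cathepsin gene Ctss (0.51 ± 0.09). Ctss was at 0.0726 with the values as deposited (adjusted p = 0.894) and at -0.0511 with each array centred on its median. The list call was lost without TGFb1 replicate 2. Without progesterone replicate 2, where S100a8 was at 2.01, the calls of the list's members were lost as well. In all arrays 3 members passed by limma, and 6 had an unadjusted p under 0.05. Antigen presentation class II genes had 4 up and 1 down of 8 (median 0.83; camera adjusted p = 0.0158, and adjusted p = 0.407 with an estimated correlation; the same counts when adjusted over the list alone). H2-Aa rose by 2.44 ± 0.19, Cd74 by 2.00 ± 0.16, Cd40 by 1.64 ± 0.15 and H2-Eb1 by 1.49 ± 0.20, while the brightest members H2-DMa (-0.26 ± 0.11) and H2-Ab1 (0.17 ± 0.13) did not pass. Without _x_at and _s_at probe sets the list had an adjusted p = 0.0969. Other large rises were of the macrophage chitinase-like gene Chil3 (4.42 ± 0.67), the platelet factor gene Pf4 (3.12 ± 0.26), the lysozyme gene Lyz1 (3.43 ± 0.60, and 2.28 without TGFb1 replicate 2), the mast cell protease genes Mcpt2 (2.72 ± 0.20) and Mcpt1 (2.71 ± 0.14), the class II gene H2-Ea (2.38 ± 0.19) and the uridine phosphorylase gene Upp1 (2.43 ± 0.21). Lyz1 and Lyz2 are close paralogs whose probe sets can share signal, so their separate values are uncertain. The deposited signals of Chil3 were 182 and 14.4 in the TGFb1 arrays and 1409 and 1336 in the progesterone arrays.

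Mast cell and basophil markers had 2 of 6 up, Kit (1.09 ± 0.16) and Ms4a2 (0.96 ± 0.23, and 0.64 without TGFb1 replicate 2), also when adjusted over the list alone, and were not called as a list (adjusted p = 0.129), but were called as higher without TGFb1 replicate 1 (adjusted p = 0.00395), without progesterone replicate 1 (adjusted p = 0.0288) and with each array centred on its median (adjusted p = 0.0167), with the brightest members Cpa3 at -0.33 ± 0.20 and Fcer1a at 0.49 ± 0.20. B cell markers had 1 of 5 down, Ighm (-0.92 ± 0.10, with its probe sets between -0.92 and 0.20), and Cd79b was at 0.16 ± 0.25. That count was the same when adjusted over the list alone. NK and gamma delta T cell markers had 1 of 5 down, Klrd1 (-0.67 ± 0.12), with 2 down when adjusted over the list alone, and Trgv4 was at -0.14 ± 0.15, with its probe sets between -1.42 and -0.14. Neither of the 2 tested CD8 T cell markers passed, with Cd8a at -0.16 ± 0.22 and Cd8b1 at -0.31 ± 0.24. The only tested stromal and endothelial marker was Pecam1, which fell by 0.97 ± 0.17, and no erythroid marker lay above the level filter. The ratio of 3 prime to 5 prime signal, a sign of RNA quality, was on the log2 scale -0.42 and -0.49 (TGFb1) and -0.54 and -0.52 (progesterone) for Gapdh, and 0.32 and 0.29 (TGFb1) and 0.36 and 0.40 (progesterone) for Actb.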

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

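Leaving out the X and Y chromosome genes was chosen after seeing the data; it gave 822 genes changed, 1323 probe sets changed, 392 genes separated and 12 lists. Counts of changed genes moved beyond 1.5 times from 857 with each array centred on its median (3779), with no filter (488), with no intensity trend (464), at an adjusted p under 0.10 (1362) and with at least 2-fold (386). Probe sets changed moved from 1348 to 5543, 534, 481, 2177 and 656 under these, and to 829 with the upper 25% by level. Genes separated moved from 405 to 225 with a pseudocount of 64, 179 with the upper 25% and 1152 at 1.5-fold with no overlap. Lists changed went from 12 to 0 with an estimated correlation, on 2 residual degrees of freedom, and to 5 with the fry direction test. Fry called the TGFb response, homing receptor, cholesterol synthesis, fatty acid synthesis and class II lists. It did not call the cell cycle list (fry adjusted p = 0.106). A stricter or looser threshold explains the counts under those settings by construction. For the others, those with fewer or more tested genes among them, the cause was not tested. Leaving out each array in turn gave 246 to 1215 genes changed, 323 to 1646 probe sets changed, 402 to 541 genes separated and 9 to 14 lists.

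The mean signal of the 18S ribosomal RNA control probe sets was 99.7 (TGFb1) and 105 (progesterone) in arrays of replicate number 1. It was 35.2 and 51.7 in those of replicate number 2, and the cause was not tested. The replicate number shares 2 values between the groups and the labels do not say what it marks. With it as a replicate block, 1936 genes and 3152 probe sets changed and 12 lists were called, Foxp3 passed as a fall (-0.37, adjusted p = 0.0128), and the replicate differences of the groups correlated at r = 0.205 over genes. Of the 857 genes, 857 were called with the block, 638 with the values as deposited and 655 with centring, none with the opposite sign. Directions that turned for called results came from scaling, relative to all-gene medians of -0.22 (as deposited) and -0.34 (centred), and the cause beyond this shift was not tested. With the values as deposited, Stat3 was at -0.0306, Foxo1 -0.0478, Igtp -0.0303 and Xbp1 -0.0256, and the medians of Th17 genes -0.0776, quiescence genes -0.27, homing receptor genes -0.0786 and ribosome biogenesis genes -0.0217. With centring, Stat3 was at -0.15, Foxo1 -0.17, Igtp -0.15, Xbp1 -0.15, Slfn2 -0.11 and Ctss -0.0511, and the medians of quiescence genes -0.40, homing receptor genes -0.20 and ribosome biogenesis genes -0.15. For homing receptor genes and, as deposited, Th17 genes the test was upward while the median was negative. Of 1951 values of named genes under alternatives, 1657 kept direction and call, 188 lost and 77 gained the call. Of 431 list medians, 371 kept both. Signal over background limits dim genes, whose folds are understated.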

Other observations

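Gene families, grouped by symbol and tested after the data were seen, added 2 calls among 154 families. Kinesin genes (Kif) had 9 of 27 down with a median of -0.19 (camera adjusted p = 0.0185), and 1 of them is in a list described above. Minichromosome maintenance genes (Mcm), which unwind DNA for replication, had 4 of 10 down with a median of -0.50 (camera adjusted p = 0.0185), and 6 of them are in such a list. With an estimated correlation both had an adjusted p = 0.997.

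All tests of the patterns below were chosen after the patterns were seen. For dilution by other cells and for more myeloid cells, the gene lists and the bounds were set then, but before the values of those lists were seen. The effect of progesterone, which the labels name, was not tested apart from the differences below.

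Xist was high and Y-linked genes were low in both progesterone arrays. Cells from animals of different sex in the groups would lower every expressed Y-linked gene. The smallest gap between the groups over the 4 tested Y-linked genes was 1.55 on the log2 scale. That gap is part of the pattern itself, so it is no separate test. Without the level filter, which adds dim genes, 3 of 6 listed Y-linked genes fell and 2 were higher with progesterone. The median of genes that escape X inactivation depended on scaling (0.36, 0.0397 as deposited and -0.084 with each array centred on its median, where the bound of 0 set for it was missed). Less the median of all genes it was 0.26 both as deposited and with centring. Xist differed by at most 0.37 within a group, but that is part of the pattern itself, so an array exchanged between the groups was not tested by it. A candidate explanation is that the TGFb1 cells came from male and the progesterone cells from female animals.

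Cell cycle genes were lower with progesterone. A difference in array brightness or its normalisation is argued against, since with the values as deposited the list median less that of all genes was -2.25 over the 28 members tested with quantile normalisation, and -2.12 over the 29 that passed the level filter as deposited. Dilution of T cells by other cells would lower T cell identity genes as far, and their median was -0.045 with an SD of 0.30 over 18 genes, of which 1 fell and none rose. With scaling it moved to -0.46 as deposited, where 2 of the 18 fell, and to -0.59 with centring, where 16 fell. The latter median is below the bound of -0.5 set for the test. Less the median of all genes it was -0.25 in both, against -2.12 for the cell cycle genes. What stays open is the sex of the animals or another difference between the cultures besides progesterone, since 0 arrays carried the sex-linked pattern of the other group, so treatment and sex cannot be told apart.

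Myeloid and class II genes were higher with progesterone. More myeloid cells left in the cultures may account for this, but a second myeloid list had a median of 0.0557 with none of 10 genes up by limma and 1 at an unadjusted p under 0.05. The median was -0.16 as deposited and -0.29 with centring, with 1 gene up in each and 4 down with centring. A median below 0 had been set as evidence against this source, but less the median of all genes the list median was 0.0539 in both. This decides little, since many of its genes are dim, and without the level filter 13 of its 20 genes were higher with progesterone. B cells left in the cultures were tested with the B cell markers, with a median of 0.42 and none up. Ighm, the marker above the floor, fell by 0.92, and by the bounds first set the test went against B cells. The fall of Ighm decides little, since its signal may not follow B cells. In the TGFb1 arrays its deposited signals were 3810 and 4081, against 40.7 and 38.1 for Cd79b. Another Ighm probe set was at 0.20. Cd79a (0.71), Cd22 (0.47), Blk (0.42) and Cd79b (0.16) were higher with progesterone, but none of them passed. The reservation that markers near the floor exclude nothing was added after the result was seen, and under it these sources cannot be told apart. The labels name the cells CD4+, and a sort for that would remove most cells of either kind, but how far it did so was not tested. The mast cell and basophil marker Cpa3 had deposited signals of 1147 and 700 in the TGFb1 arrays and 540 and 548 in the progesterone arrays. Mast cells as a source of the rises of Mcpt1 and Mcpt2 were not tested.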
